A study of Mus musculus with 24 samples.

How the data were processed

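Total RNA from MC38 cells carrying a control guide (guide 1 or guide 2) or an Ado guide (guide 1 or guide 2), untreated or treated with TNF for 1 h or 6 h, was profiled with a QuantSeq 3' mRNA kit in 24 libraries, 2 per guide population and treatment. The submitters' processing notes name FastQC, cutadapt 1.7, HISAT2, featureCounts, Subread and limma and the genome builds GRCm38 and mm10, and other versions and the order of the steps are not stated. The deposited table holds log2 CPM values (tag counts scaled to a common total) for each gene, which the authors had normalised. The unit and the normalisation were inferred from the values: the unlogged values of each library summed to between 998900 and 999014, and all libraries shared a lowest value of -3.349 and a highest value of 17.04, as after quantile normalisation. The table had 0 missing values, 0 identical pairs of libraries and 0 further columns per library. The gene Gm42418 was the highest in every library, at 13.4% of the sum. This share is fixed by the shared highest value, so it cannot show whether the level of Gm42418 differed between libraries.

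No library size was stated. From the spacing of low values, taking an offset of 0.5 and whole tags between counts of 10 and 20, the depth was estimated at 4260000 to 6630000 tags per library. At this depth 617 to 1013 genes per library stood at the lowest value, where log2 differences are bounded by the scale and carry little precision. Replicates of 1 guide and treatment correlated across genes at 0.963 to 0.976 and libraries of different guides of 1 group at 0.959 to 0.975; genes are not independent replicates.

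Values were used as deposited. Genes were kept when they reached 0 on the log2 scale in at least 4 libraries, which left 13272. Limma 3.58.1 in R 4.3.3 with statmod 1.5.0 fitted 6 group means of 4 libraries with the guide population (4) as a random block, at an estimated correlation of 0.0485, and moderated variances with a trend on the mean. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all genes kept. The comparisons were TNF at 1 h and 6 h against untreated in each genotype, Ado KO against control at each time, and the interactions of genotype and TNF. The guides of 1 genotype were compared on 12 means of guide and treatment. These 12 means also gave the counts with guide populations as fixed terms, where only libraries of 1 guide and treatment set the error. Replicate numbers were not used as pairs, since deviations of replicates with the same number correlated between treatments at -0.158 to 0.054. For control guide 2 at 1 h the sample titles and the deposited column names give opposite replicate numbers; each column was joined to the sample whose description names it, and numbers here follow the titles, so 2-1 is the column numbered 2 and 2-2 the column numbered 1.

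Of 21 gene lists fixed in advance 20 had at least 5 measured members and were tested with limma's camera, with the preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. The lists were NF-kB feedback, chemokines and cytokines, immediate-early and MAPK feedback, adhesion with acute phase and proteases, interferon-stimulated genes, class I presentation, TNF receptor signalling and cell death, hypoxia, NRF2 and glutathione, cysteamine with taurine and coenzyme A, the Arg/N-degron pathway, p53 targets, ATF4 and unfolded protein response, S phase and G2/M, sterol synthesis, extracellular matrix, epithelial, immune, endothelial and pericyte, mitochondrially encoded and housekeeping. The mean response of the NF-kB lists was compared between 2 control and 2 Ado populations by an exact permutation test. Genes named in the text followed a rule: Ado; the 10 largest rises and 10 largest falls among called genes with the same sign in every guide population compared, leaving out unnamed models; and up to 4 members of each list with the smallest adjusted p plus members moving against their list. A gene named in 1 comparison may be given in others. The comparisons, tests, lists, naming rule and most alternatives were set before the data were examined.

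Biotypes and positions came from GENCODE M21 (GRCm38), in which 15217 symbols matched 1 gene, 41 several and 132 none. Small non-coding RNAs without a similar transcript of another gene (85% identity over 50 bases) were found with blastn 2.17.0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The fit was tested on simulated data with 13272 genes, where it recovered 49.3%, 74.6% and 86.4% of genes changed by 1.5, 2 and 4-fold in the control 1 h comparison, with 6 false calls of 146. For the 6 h interaction it recovered 14.9%, 46.3% and 81.8%, with 3 false calls of 98. For genotype in untreated cells it recovered 49.3%, 62.7% and 89.4%, with 8 false calls of 142. The simulated data were given a guide correlation close to the 0.0485 of the real data, and the fit estimated 0.0060 to 0.0099 from them. The estimate can thus fall below the true value. If the 0.0485 is also too low, the p-values for genotype are too small, which was not tested. The simulated false calls may therefore not carry over.

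The alternatives were other scalings between libraries, no filter and a stricter filter, other variance models, other ways to treat guide populations and replicate numbers, only the groups compared in the fit, a 2-fold threshold, and leaving out each library or guide. Protein-coding genes alone and the guide population as an additive term were added after the data were seen, as were the comparisons of 6 h with 1 h. A pseudocount and tests on counts were left out because the deposited values are already on a log2 scale and are not counts.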

Results

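RNA from MC38 cells, a mouse colon carcinoma line, was profiled by 3' tag sequencing in 24 libraries. The cells carried a control guide RNA (guide 1 or guide 2) or a guide RNA against Ado (guide 1 or guide 2), which gives 4 guide populations. Ado encodes a thiol dioxygenase that oxidizes cysteamine and the N-terminal cysteine of some proteins. Each population was left untreated or given the cytokine TNF for 1 h or 6 h, in 2 libraries per population and treatment, so that each of the 6 groups of genotype and treatment held 4 libraries. Libraries are named below by guide number and replicate number, so that 2-1 is replicate 1 of guide 2. The deposited table gave normalised log2 CPM values (tag counts scaled to a common total, CPM) for each gene, and 13272 genes passed the filter on low values. The depth was not stated. The steps between low values placed it at an estimated 4260000 to 6630000 tags per library, and 617 to 1013 genes per library stood at the lowest value. Replicates of the same guide and treatment correlated across genes with r from 0.963 to 0.976. Nothing in the labels says that replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

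Ado itself (GRCm38 chromosome 10, 67544511 to 67548955, minus strand) was read at a similar level in all groups. Its mean in control cells was 5.26 ± 0.08 log2 CPM untreated, 5.19 ± 0.15 at 1 h and 5.14 ± 0.10 at 6 h (SD, n = 4). In the cells with Ado guides it was 5.35 ± 0.09, 5.35 ± 0.16 and 5.30 ± 0.20 (SD, n = 4). The difference in the untreated cells was 0.09 ± 0.11 (SE; limma adjusted p = 0.889), and it was 0.16 ± 0.11 at both later times (adjusted p = 0.484 and 0.63). The 24 libraries lay between 5.00 and 5.53. A tag near the 3' end need not change when a guide introduces a small insertion or deletion in the coding sequence, so this level checks neither the editing nor the labels. The groups are called Ado KO below because the labels give that genotype.

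The first comparison asked what 1 h of TNF did in control cells. The largest rises named here were those of the NF-kB targets Cxcl1, Tnfaip3 and Nfkbia. Cxcl1 (chromosome 5, 90891241 to 90893115), a neutrophil chemokine, went from 1.15 ± 1.42 to 6.72 ± 0.79 log2 CPM (SD, n = 4), a log2 fold change of 5.57 ± 0.38 (SE; adjusted p = 5.5e-12). Untreated, Cxcl1 was at -0.89 in library 1-1 and at 1.31 to 2.31 in the other 3, and without that library the change was 4.93. Nfkbia (chromosome 12, 55489410 to 55492647), which encodes the inhibitor IkB-alpha, went from 7.54 ± 0.16 to 10.63 ± 0.25 (SD, n = 4). Its log2 fold change was 3.10 ± 0.08 (SE; adjusted p = 1.0e-23). Tnfaip3, which encodes the ubiquitin-editing feedback protein A20, rose by 4.20 ± 0.39 (SE) from a level of -0.98, close to the bottom of the scale. Zfp36, whose product destabilizes cytokine messages, rose by 2.48, the AP-1 gene Junb by 2.38, the monocyte chemokine gene Ccl2 by 2.25 and the transcription factor gene Irf1 by 1.79.

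By list at 1 h in control cells, 13 of 34 measured immediate-early and MAPK feedback genes rose, among them Junb, Ier3 (1.75), Ier5 (1.11) and Jun (0.90), and 20 did when adjusted over the list alone. Of 11 chemokine and cytokine genes 4 rose, namely Cxcl1, Ccl2, Cxcl10 (1.45) and Csf1 (0.78), and 7 when adjusted over the list alone. Of 27 NF-kB feedback and subunit genes 3 rose, namely Nfkbia, Tnfaip3 and Relb (0.43), and 7 when adjusted over the list alone. Vcam1, an adhesion molecule, rose by 0.97 as the only called member of 19 adhesion, acute phase and protease genes. Btg2, an antiproliferative p53 target, rose by 2.28 as the only called member of 24 p53 targets, of which 6 rose when adjusted over the list alone. Falls were few and smaller. They included Id1 (-0.88) and Id3 (-0.44), which encode inhibitors of basic helix-loop-helix factors, Osgin1 (-1.77, from a level of 1.68 to -0.08), Ier5l (-0.67), Commd9 (-0.81), Derl2 (-0.44) and the ribosomal protein genes Rpl12 (-0.30) and Rpsa (-0.23). With each of the 8 libraries left out in turn, the calls of Osgin1, Id3, Derl2 and Rpl12 ended in 6 of the fits, those of Commd9 and Rpsa in 5, Relb in 4, Id1 in 3 and Ier5l in 1. The set test camera called 6 of 20 lists, of which 5 held with an estimated correlation: immediate-early (adjusted p = 1.8e-30, then 4.3e-07), chemokines (4.4e-14, then 0.00161), NF-kB feedback (2.1e-09, then 1.4e-05), p53 targets (6.2e-04, then 0.00272) and adhesion (0.0156, then 0.0262). The list of 13 mitochondrially encoded genes, higher by a median of 0.31 with no member past the threshold by limma (8 higher and 2 lower at an unadjusted p below 0.05), was called at adjusted p = 5.1e-04, and at adjusted p = 0.0673 with an estimated correlation. In 1 library of this group, 1-2, mitochondrial messages made up 3.58% of the summed values, against 2.55 to 2.66% in the other 3.

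In all, limma called 52 genes at 1 h in control cells, 44 higher and 8 lower. With guide populations as fixed terms it called 216, 172 higher and 44 lower. The count was 31 without control untreated 1-1, 34 without control untreated 1-2 and 84 without control TNF 1 h 2-1, and 22 without guide 1 and 260 without guide 2.

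In Ado KO cells the largest rises at 1 h named here were again those of Cxcl1, Tnfaip3 and Nfkbia. Nfkbia rose by 3.13 ± 0.08 (SE; adjusted p = 7.5e-24), from 7.50 ± 0.08 to 10.63 ± 0.08 (SD, n = 4). Cxcl1 rose by 4.74 ± 0.38 (SE; adjusted p = 2.9e-10), Tnfaip3 by 3.82, Dusp8 by 2.59, Zfp36 by 2.58, Junb by 2.18, Ccl2 by 1.55 and Irf1 by 1.63. Dusp1, a phosphatase that switches off MAP kinases, rose by 2.07. Of the immediate-early list 13 of 34 rose (14 higher and 1 lower when adjusted over the list alone), of the chemokines 3 of 11 (6), of the NF-kB feedback genes 2 of 27 (9), of the adhesion list 1 of 19 (2) and of the p53 targets 2 of 24 (4), the last being Btg2 (2.50) and Cdkn1a (0.68), a cell cycle inhibitor. Ddit3, a stress transcription factor gene, rose by 0.51. Man2a1, a Golgi mannosidase gene, fell by 0.65. When 1 of the 8 libraries was left out at a time, the calls of Man2a1 and Ddit3 ended in 6 of the fits, Ccl2 in 5 and Cdkn1a in 4.

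Camera called these 5 lists in Ado KO cells at 1 h, and each held with an estimated correlation (adjusted p = 4.0e-07 for immediate-early, 9.9e-07 for NF-kB feedback, 0.00158 for p53 targets, 0.00434 for chemokines and 0.0182 for adhesion). Limma called 34 genes, 32 higher and 2 lower, and 57 with guide populations as fixed terms, 53 higher and 4 lower, and 15 without Ado guide 2. Of the genes higher at 1 h, 26 were called in both genotypes, where independent lists of 44 and 32 genes would share 0.106. Of the genes lower at 1 h, 8 in control and 2 in Ado KO cells, 0 were called in both by limma, and 43 of the 52 genes called in control cells had the same sign in Ado KO cells. No gene was called in opposite directions, and the 2 comparisons share no library.

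**Figure D1:**
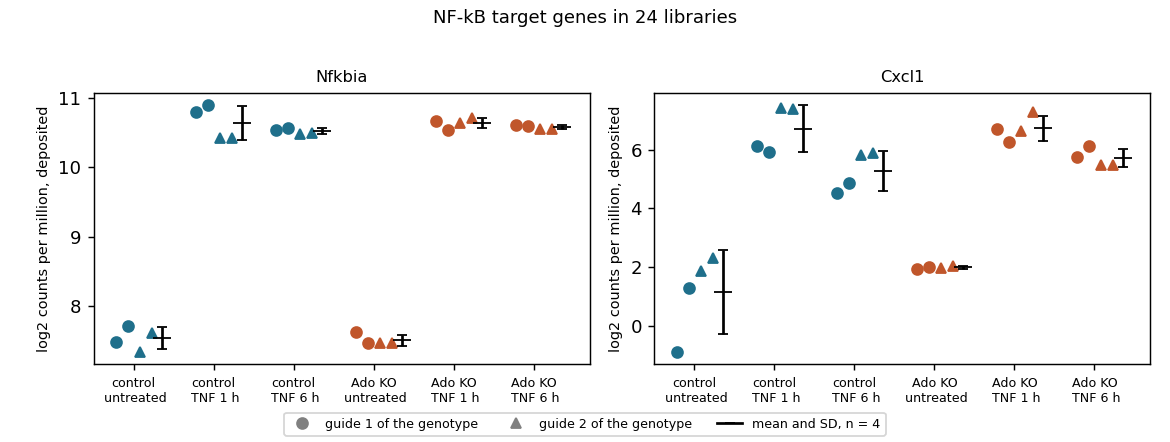
Log2 CPM (y axis) of Nfkbia and Cxcl1 in each library by group (x axis); circles are guide 1 and triangles guide 2 of the genotype, blue is control and orange Ado KO, and black marks give the mean and SD (n = 4). Nfkbia stood at 7.54 ± 0.16 in untreated and 10.63 ± 0.25 in 1 h control libraries (SD), and at 7.50 ± 0.08 and 10.63 ± 0.08 in Ado KO.

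After 6 h of TNF, control cells held high levels of NF-kB targets. The labels give no time for the untreated libraries, and no untreated 6 h library was among those analysed. For every gene at 6 h, in either genotype, an effect of TNF therefore cannot be told apart from time in culture or handling. Ccl2 rose from 6.02 ± 0.58 to 10.02 ± 0.10 log2 CPM (SD, n = 4), a log2 fold change of 4.00 ± 0.32 (SE; adjusted p = 1.4e-11). Vcam1 (chromosome 3, 116109949 to 116129688) rose by 2.59 ± 0.09 (SE; adjusted p = 1.8e-20) and Nfkbia by 2.99 ± 0.08 (SE; adjusted p = 5.2e-24). Lif, a cytokine of the interleukin 6 family, rose by 4.78 ± 0.62 (SE) from -1.24, a level near the bottom of the scale. Without control untreated 1-1 Lif rose by 4.07. Of the chemokines and cytokines 10 of 11 rose, including Cxcl10 (2.41), Csf1 (1.94) and Ccl5 (1.28). Of the NF-kB feedback genes 14 of 27 rose, including Relb (1.82), Traf1 (1.62) and Tnip1 (1.52). Of the adhesion list 11 of 19 rose, including Plau (2.56), which encodes urokinase, and the prostaglandin synthase gene Ptges (1.12). Of the immediate-early list 21 of 34 rose, including Junb (2.17), Egr1 (1.91), Ier5 (1.62) and Ier3 (1.44). Adjusted over the list alone the numbers were 10 chemokines, 14 NF-kB feedback genes with 1 lower, 12 of the adhesion list and 24 of the immediate-early list.

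Of 41 interferon-stimulated genes 11 rose in control cells at 6 h and 29 were not called (camera adjusted p = 3.5e-05, and 0.0518 with an estimated correlation). Those that rose included Parp14 (1.34), Irf1 (1.21), Ifit3 (0.99) and Rsad2 (0.80), and Irf9, which encodes a subunit of the interferon-activated complex ISGF3, fell by 0.27 (14 higher and 1 lower when adjusted over the list alone). Of 24 p53 targets 8 rose and 2 fell, the same numbers as when adjusted over the list alone. Btg2 rose by 2.80, Cdkn1a by 1.31 and Mdm2, which encodes the ubiquitin ligase of p53, by 0.86, while Phlda3 (-0.52) and Ei24 (-0.33) fell. Of 41 genes of TNF receptor signalling and cell death 5 rose and 3 fell (6 and 3 adjusted over the list alone). Those that rose included the pro-apoptotic Bid (0.66) and the death receptor gene Tnfrsf10b (0.59), which is also on the p53 list, and those that fell were Casp9 (-0.98), Map3k14 (-0.90) and Bcl2l1 (-0.33). Rgs16, a regulator of G protein signalling, rose by 3.14 as the only called member of 14 genes of the Arg/N-degron pathway and its cysteine substrates (1 adjusted over the list alone). H2-Q4 rose by 1.23 and the chaperone gene Calr fell by 0.24, the 2 called of 22 class I antigen presentation genes (also 1 and 1 adjusted over the list alone); members of the H2-Q family share near-identical sequence, so H2-Q4 is uncertain.

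Among metabolic and growth lists in control cells at 6 h, camera called sterol synthesis, as lower (adjusted p = 2.1e-04, and adjusted p = 0.0678 with an estimated correlation), and not hypoxia (0.71), NRF2 and glutathione (0.313) or the cysteamine list (0.103). Of 27 genes on the sterol synthesis list 12 fell and none rose by limma (13 lower and 1 higher when adjusted over the list alone). Those that fell included Mvd (-0.63), Fdft1 (-0.50), the fatty acid desaturase gene Scd2 (-0.64) and the regulator gene Insig1 (-0.63). Of 34 hypoxia-inducible genes 3 rose and 8 fell (3 and 10 adjusted over the list alone). Ndrg1 rose by 1.66, Hk2 by 0.66 and Vegfa by 0.58, and Ddit4, an inhibitor of mTORC1, fell by 1.79. Of 27 NRF2 and glutathione genes 2 rose and 4 fell (2 and 5 adjusted over the list alone), with the cystine transporter gene Slc7a11 up by 1.46 and the ferritin gene Ftl1 at -0.37. Of 16 genes of cysteamine, taurine and coenzyme A metabolism 1 rose and 4 fell (2 and 6), of 34 ATF4 and unfolded protein response genes 1 rose and 1 fell (Atf4 at 0.19 and Trib3 at -0.46; neither when adjusted over the list alone), and of 38 S phase and G2/M genes 1 rose and 7 fell (1 and 7). Of 30 extracellular matrix and mesenchymal genes 3 rose and 5 fell (3 and 6), with the transcription factor gene Zeb1 at 1.15, Zeb2 at 0.77, Col3a1 at -0.66 and Fn1 at -0.41. Of 17 housekeeping genes 6 fell (6 adjusted over the list alone), including Actb (-0.46). Among markers of other cell types, none of 11 immune genes passed by limma (0 adjusted over the list alone; 1 lower at an unadjusted p below 0.05), nor did either of 2 epithelial genes (1 lower adjusted over the list alone and 1 at an unadjusted p below 0.05), and Pdgfrb (-1.48) and Eng (-1.78) fell among 5 endothelial and pericyte genes (2 adjusted over the list alone).

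Small non-coding RNAs rose in control cells at 6 h. Of 346 measured small nuclear, nucleolar, Cajal body, ribosomal and other structural RNAs, 266 were higher and none lower by limma (301 higher and none lower at an unadjusted p below 0.05), with a median log2 fold change of 2.17. Rn7sk (chromosome 9, 78175303 to 78175633, minus strand), the RNA that holds the elongation factor P-TEFb inactive, went from 5.24 ± 0.37 to 12.18 ± 0.40 log2 CPM (SD, n = 4), a change of 6.94 ± 0.17 (SE; adjusted p = 6.9e-25). Rpph1, the RNA of ribonuclease P, rose by 5.05 ± 0.20 (SE), the nucleolar RNA Snord118 by 5.55 and Snora74a by 5.01. Rmrp (6.26) shares its name between 2 annotated genes and is uncertain. These RNAs took 2.18 to 3.35% of the summed values in the 4 control libraries at 6 h, against 0.264 to 0.305% in the untreated control libraries. Replication-dependent histone messages rose with them (40 higher and 1 lower of 64, median 1.61), chiefly H3 (12 of 12), H2B (13 higher and 1 lower of 14) and H4 (11 of 13), while 4 of 20 H2A genes rose and none of 5 H1 genes passed by limma (0 at an unadjusted p below 0.05). Histone genes share near-identical copies, so single members are uncertain. Mitochondrially encoded messages were higher for 10 of 13 genes (12 adjusted over the list alone), with mt-Nd5 at 2.06 and mt-Co1 at 1.02.

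In all, limma called 2392 genes at 6 h in control cells, 1027 higher and 1365 lower, and 1583 without control untreated 1-1, 684 without guide 1 and 1575 without guide 2. Restricted to 10746 protein-coding genes without histone genes and normalised again, a setting chosen after the data were seen, it called 692 higher and 722 lower, where the same genes gave 617 higher and 1190 lower before. Under that setting sterol synthesis had 8 lower and 1 higher genes, hypoxia-inducible genes 4 lower and 3 higher, NRF2 and glutathione 4 lower and 4 higher, the cysteamine list 2 lower and 2 higher, and housekeeping 2 lower. Camera called 9 lists at 6 h in control cells. Higher with either correlation were chemokines (adjusted p = 8.1e-18, then 3.3e-04 with an estimated correlation), immediate-early (2.0e-22, then 2.1e-06), NF-kB feedback (7.7e-17, then 3.2e-07), adhesion (2.0e-10, then 7.9e-06), mitochondrially encoded (1.1e-12, then 5.6e-04) and p53 targets (0.00516, then 0.0102). Interferon-stimulated genes (3.5e-05), sterol synthesis as lower (2.1e-04) and class I presentation (0.0269) had an adjusted p of 0.0518, 0.0678 and 0.16 with an estimated correlation. Among the largest falls, Etv1 (-2.45) and Atoh8 (-2.55) started at 3.10 and 2.10, while Rfx2, Lhx9, Tex19.1, Mrgprf, Tnnc1, Trib2 and Gramd2 started below 1 and ended near the lowest value, which leaves the size of their fall undefined. With each of the 8 libraries left out in turn, the calls of Irf9, Ei24 and Trib3 ended in 5 of the fits, Bcl2l1 in 4, Col3a1 and Fn1 in 2, and Atf4 and Zeb2 in 1.

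**Figure D2:**
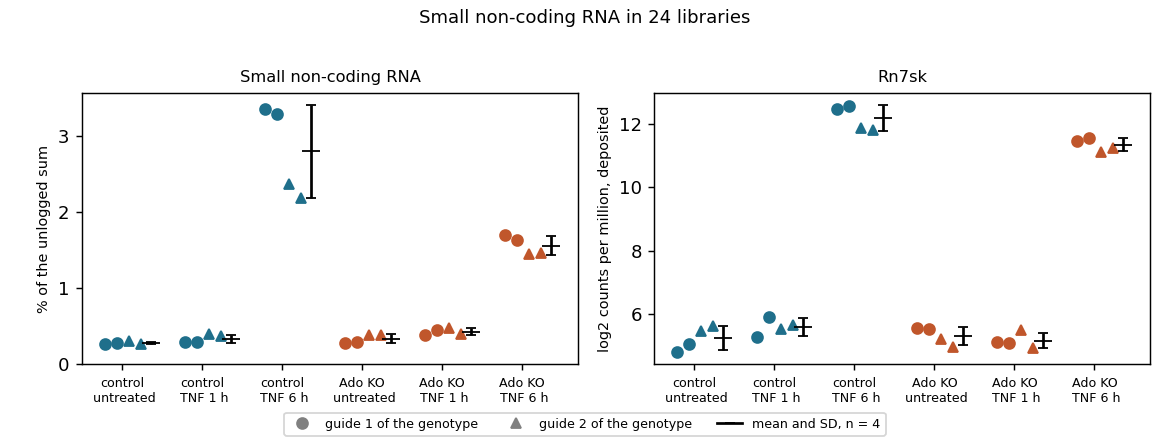
Share of the unlogged values per library taken by small non-coding RNA (left, percent) and log2 CPM of Rn7sk (right), by group; circles are guide 1 and triangles guide 2, blue is control and orange Ado KO, and black marks give the mean and SD (n = 4). The share was 2.18 to 3.35% in control and 1.44 to 1.7% in Ado KO libraries at 6 h and at most 0.471% in every other library.

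NF-kB targets were also high in Ado KO cells at 6 h. Ccl2 rose by 4.02 ± 0.32 (SE; adjusted p = 2.6e-11), Nfkbia by 3.08 ± 0.08 (SE; adjusted p = 1.3e-23), Vcam1 by 2.47 and Lif by 4.86 (4.04 without Ado KO untreated 2-2). Nfkbie, which encodes IkB-epsilon, rose by 3.31, Cxcl1 by 3.73, Cxcl10 by 2.95 and Csf1 by 2.09. Rsad2 rose by 1.57, Parp14 by 1.59, Irf1 by 1.47 and Ifit3 by 1.41. Rgs16 rose by 3.50 and Rgs2, another Arg/N-degron list member, fell by 1.47. Ndrg1 rose by 2.13, and Ddit4 (-1.95), the circadian gene Dbp (-2.05), Atoh8 (-2.32) and the sulfotransferase gene Chst1 (-2.02, from 5.69 to 3.67) fell.

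By list in Ado KO cells at 6 h, 15 of 27 NF-kB feedback genes, 9 of 11 chemokines, 10 of 19 adhesion genes and 10 of 41 interferon-stimulated genes rose (17, 9, 12 and 13 adjusted over the list alone). Of the immediate-early genes 18 rose and Klf2 (-0.73) fell (22 and 1 adjusted over the list alone). Of the p53 targets 7 rose and Phlda3 (-0.51) fell (8 and 1). Of the class I list 3 members rose (6), among them Tapbp (0.30) and Cd274 (1.30). Cd274 was on that list but encodes the checkpoint ligand PD-L1, which does not present antigen. On the sterol synthesis list 7 of 27 genes fell (9 adjusted over the list alone), with Insig1 at -0.69 and Scd2 at -0.56. S phase and G2/M genes fell in 4 of 38 (4), with Plk1 at -0.26. Cysteamine, taurine and coenzyme A genes fell in 3 of 16 (3), with Coasy at -0.33. Mitochondrially encoded messages rose in 4 of 13 (9), with mt-Nd5 at 1.41 and mt-Co1 at 0.66. Small non-coding RNAs were higher in 158 of 346 and lower in none by limma (223 and 2 at an unadjusted p below 0.05), with a median of 1.21 and Rn7sk at 6.03 ± 0.17 (SE). They took 1.44 to 1.7% of the summed values, against 0.284 to 0.388% in the untreated Ado KO libraries. Of 64 histone genes 24 rose and 4 fell, the 4 all being of the H2A class. When 1 of the 8 libraries was left out at a time, the call of Cd274 ended in 8 of the fits, Coasy in 4, Tapbp in 3 and Plk1 in 1.

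Limma called 855 genes in Ado KO cells at 6 h, 587 higher and 268 lower, and 369 without Ado guide 1 and 417 without Ado guide 2. Camera called 11 lists, of which 8 held with an estimated correlation, namely NF-kB feedback, chemokines, immediate-early, adhesion, interferon-stimulated (adjusted p = 0.00569), p53 targets (0.00148), mitochondrially encoded (0.00218) and, as lower, sterol synthesis (0.0467). Class I presentation, S phase and G2/M and the cysteamine list had an adjusted p of 0.085, 0.0952 and 0.127 with an estimated correlation. Of the genes called in both genotypes at 6 h, 499 were higher in both and 192 lower in both, where independent lists would share 45.4 and 27.6, and none was called in opposite directions. Among protein-coding genes without histone genes, 278 were higher in both and 186 lower in both, against 20.6 and 28.3. Small non-coding RNAs gave 157 of the shared rises, against 121 for independent lists. Of the 2392 genes called in control cells, 2245 had the same sign in Ado KO cells. Over 38 genes of the NF-kB feedback and chemokine lists, the mean response at 1 h was 0.84 in control and 0.64 in Ado KO populations, and at 6 h it was 1.33 and 1.38. The differences of -0.20 and 0.05 each had p = 0.333 in a two-sided exact permutation test of 2 populations against 2, the smallest p that this design allows. At 1 h the size of the difference rested on the chemokines (-0.59), while the NF-kB feedback genes alone gave -0.04.

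Untreated Ado KO and control cells differed in few genes. Cox6a2 (chromosome 7, 128205435 to 128206387, minus strand), which encodes the muscle and heart form of a cytochrome c oxidase subunit, was lower in Ado KO, at 2.70 ± 0.43 against 4.94 ± 0.18 log2 CPM (SD, n = 4), a log2 difference of -2.24 ± 0.21 (SE; adjusted p = 6.5e-08). Sox9, a transcription factor gene of epithelial progenitors, was lower by a log2 difference of -0.61 ± 0.08 (SE; adjusted p = 1.6e-04). The chemokine gene Ccl5 was higher, at 6.93 ± 0.19 against 6.23 ± 0.06 (SD, n = 4; adjusted p = 5.4e-04), and so were the arginine transporter gene Slc7a1 (0.49) and S100a4 (0.38). Lower genes included Il34 (-0.58), a ligand of the CSF1 receptor, the collagen genes Col5a3 (-1.29) and Col18a1 (-0.62), Ndrg1 (-0.58), Plcg2 (-0.62), Rapgef3 (-1.42) and Ptgds (-2.41, from 1.29 to -1.12, close to the bottom of the scale). With each of the 8 libraries left out in turn, the calls of Ptgds ended in 7 of the fits, Col18a1 in 6, Plcg2 and Rapgef3 in 4, Slc7a1 in 3 and Ndrg1 in 2, while those of Cox6a2, Sox9, Ccl5, Il34, Col5a3 and S100a4 ended in 0.

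No interferon-stimulated gene passed limma's threshold between untreated Ado KO and control cells (10 higher and 1 lower of 41 at an unadjusted p below 0.05, 4 higher when adjusted over the list alone), yet 36 of 41 were above control and camera called the list as higher (adjusted p = 1.3e-07, and adjusted p = 0.06 with an estimated correlation). Of the class I genes 1 of 22 was lower, H2-Q7 at -0.38, a call that ended in 6 of 8 fits without a library (4 adjusted over the list alone; camera adjusted p = 0.0114, and 0.284 with an estimated correlation). Of the chemokines Ccl5 was higher and Il34 lower (3 and 1 adjusted over the list alone). Camera also called chemokines, immediate-early, ATF4 and S phase and G2/M as higher, at adjusted p = 0.0303, 0.0489, 0.0278 and 0.0161. Their adjusted p was 0.395, 0.329, 0.353 and 0.284 with an estimated correlation. Limma called 33 genes, 9 higher and 24 lower. With guide populations as fixed terms, which leaves the spread between guides out of the error, it called 132, 60 higher and 72 lower. The count of 33 became 11 without control untreated 1-1, 12 without control untreated 1-2 and 13 without Ado KO untreated 2-2. It was 2 with 1 value per guide population, 139 without control guide 2 and 3 without Ado guide 2.

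At 1 h of TNF, Cox6a2 (-2.04 ± 0.21, SE; adjusted p = 6.4e-07), Sox9 (-0.52) and Il34 (-0.45) were again lower and Ccl5 (0.85 ± 0.10, SE; adjusted p = 1.6e-05) again higher in Ado KO cells. Of 41 interferon-stimulated genes 4 were higher, namely Isg15 (0.82), Irf9 (0.45), Oas1g (0.55) and Oas1a (0.52), and 8 when adjusted over the list alone; the Oas1 genes are near-identical copies and uncertain. Among class I genes H2-D1 (-0.49) and the chaperone gene Canx (-0.35) were lower, with 7 lower and 1 higher when adjusted over the list alone. The collagen gene Col5a1 (0.99), the protease inhibitor gene Timp1 (0.59) and Penk (1.05) were higher, and the secreted protease gene Htra1 (-1.19) and the immediate-early gene Klf6 (-0.54) lower. Mitochondrially encoded messages were lower in 5 of 13 (9 lower and 2 higher adjusted over the list alone), with mt-Co2 at -0.56 and mt-Co1 at -0.40. They made up 2.55 to 3.58% of the summed values in the control libraries and 1.84 to 1.91% in 3 of the Ado KO libraries, with 2.48% in Ado KO 2-2. Nucleolar RNAs were higher in 23 of 228. No gene of the ATF4 list passed by limma over all genes (11 higher and 1 lower of 34 at an unadjusted p below 0.05), and 8 were higher when adjusted over the list alone. When 1 of the 8 libraries was left out at a time, the calls of Timp1 ended in 5 of the fits, Il34, Oas1g, Oas1a, Canx and Klf6 in 4, and Irf9, Penk and mt-Co2 in 2, while those of Cox6a2, Ccl5, Isg15, H2-D1, Col5a1, Htra1 and mt-Co1 ended in 0.

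Limma called 141 genes between the genotypes at 1 h, 70 higher and 71 lower in Ado KO. With guide populations as fixed terms, which leaves the spread between guides out of the error, it called 609, 334 higher and 275 lower. The count of 141 moved with single libraries. It went to 445 without Ado KO TNF 1 h 2-2, 30 without 2-1, 60 without 1-2 and 65 without 1-1 of that group. Without control TNF 1 h 1-1 it was 78. With only the 8 libraries compared in the fit it was 3, and with 1 value per guide population 6. Without control guide 2 it was 956, without Ado guide 1 23 and without Ado guide 2 71. Class I presentation (camera adjusted p = 2.8e-05) and mitochondrially encoded genes (6.7e-07) were called as lower and both held at adjusted p = 0.034 with an estimated correlation, while the interferon-stimulated list (0.00163) and the ATF4 list (0.0252), called as higher, had an adjusted p of 0.294 and 0.425.

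At 6 h of TNF, interferon-stimulated genes stood higher in Ado KO cells. Cxcl10, a chemokine that attracts T cells, was at 6.69 ± 0.17 against 5.61 ± 0.34 log2 CPM (SD, n = 4), a difference of 1.07 ± 0.16 (SE; adjusted p = 3.5e-04). Of 41 interferon-stimulated genes 7 were higher, including Ifit1 (0.94), Oasl2 (0.91), Ifit3b (0.91) and Isg15 (0.79), and 16 when adjusted over the list alone; Ifit3b has a close copy in Ifit3 and is uncertain. Il1rl1, the interleukin 33 receptor gene, was higher by 1.08 and Col5a1 by 0.96. Cox6a2 was lower by a log2 difference of -2.08 ± 0.21 (SE; adjusted p = 4.1e-07), and Sox9 was at -0.69 and Il34 at -0.44. Ccl5 was no longer called at 6 h, at 0.33 ± 0.10 (SE; adjusted p = 0.125), and its 6 h interaction was not called either (-0.36; adjusted p = 0.594). Over the 3 times, Cox6a2 lay between 2.12 and 3.39 in the 12 Ado KO libraries and between 4.61 and 5.35 in the 12 control libraries. Small non-coding RNAs were lower in 45 of 346, such as Snora30 (-1.09) and Snord13 (-1.13), and mitochondrially encoded messages in 2 of 13 (7 adjusted over the list alone), mt-Co1 (-0.47) and mt-Co3 (-0.48). Lars2, a mitochondrial leucyl tRNA synthetase gene, was at -1.21. With each of the 8 libraries left out in turn, the calls of Il34 ended in 6 of the fits, Oasl2, Ifit3b and mt-Co3 in 5 and Ifit1 in 4, while those of Cxcl10, Isg15, Il1rl1, Col5a1, Cox6a2, Snora30, Snord13, Lars2 and mt-Co1 ended in 0.

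The lists closest to the known reactions of Ado had no member called over all genes between the genotypes in the untreated state, at 1 h or at 6 h. Proteins and cysteamine, on which Ado acts, were not measured, so these message levels do not test its activity. Of 14 genes of the Arg/N-degron pathway and its cysteine substrates 0 were called by limma at any of the 3 times, also when adjusted over the list alone (1, 2 and 1 lower at an unadjusted p below 0.05). Of 16 genes of cysteamine, taurine and coenzyme A metabolism 0 were called, with 1 lower at 6 h when adjusted over the list alone (1 higher and 1 lower, 0 higher and 1 lower, and 1 higher and 2 lower at an unadjusted p below 0.05 at the 3 times).

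Limma called 135 genes between the genotypes at 6 h, 56 higher and 79 lower in Ado KO. With guide populations as fixed terms, which leaves the spread between guides out of the error, it called 324, 164 higher and 160 lower. Among protein-coding genes normalised again it called 38, 23 higher and 15 lower, where the same genes gave 48 higher and 18 lower before, and with 1 value per guide population 28. Without 1 library the count was 57 (control TNF 6 h 1-1), 68 (control 1-2), 75 (Ado KO TNF 6 h 1-2), 58 (2-1) or 66 (2-2), and without 1 guide it was 322 (control guide 2), 37 (Ado guide 1) or 31 (Ado guide 2). Interferon-stimulated genes as higher (camera adjusted p = 7.8e-10) and mitochondrially encoded genes as lower (1.9e-08) both had adjusted p = 0.0104 with an estimated correlation. Class I presentation as lower (0.025) and extracellular matrix as higher (0.0498) had 0.257 and 0.309 as adjusted p with an estimated correlation.

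**Figure D3:**
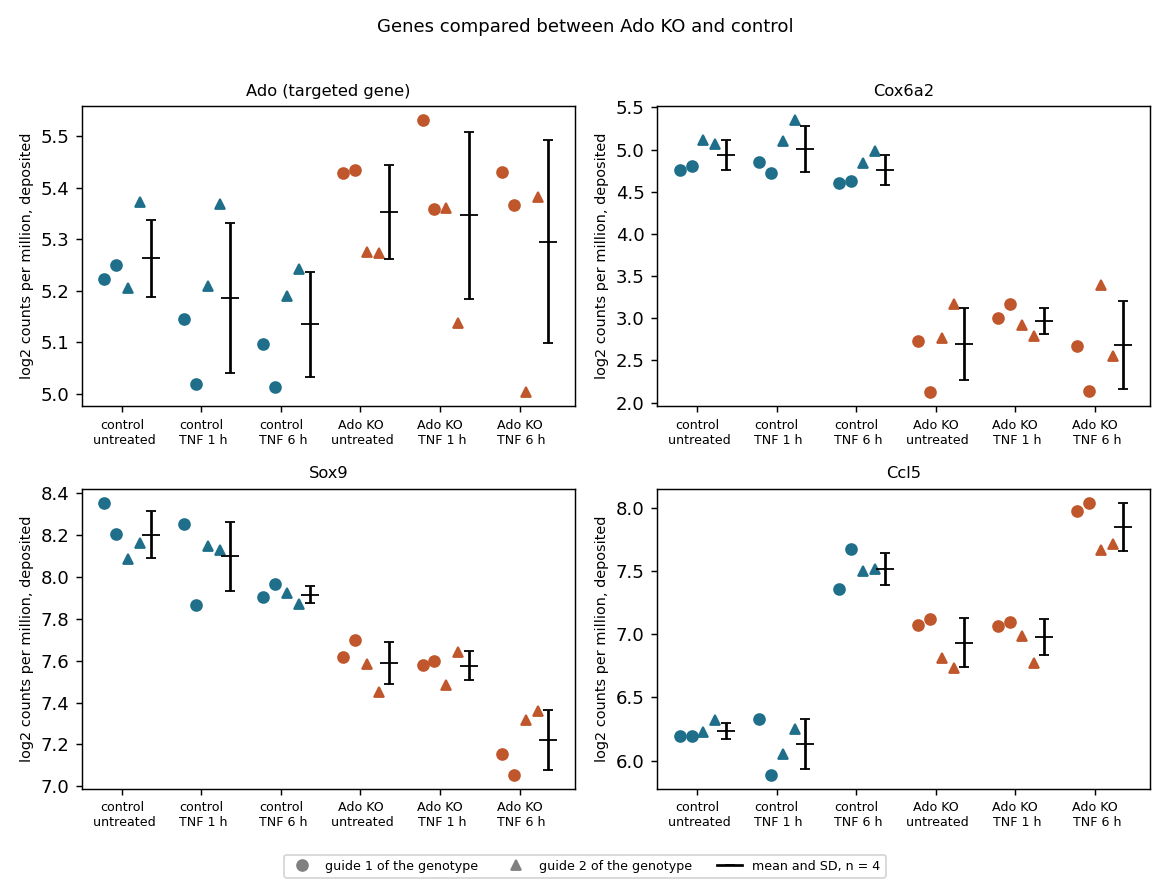
Log2 CPM (y axis) of Ado, Cox6a2, Sox9 and Ccl5 in each library by group (x axis); circles are guide 1 and triangles guide 2 of the genotype, blue is control and orange Ado KO, and black marks give the mean and SD (n = 4). Ado lay between 5.00 and 5.53 in all 24 libraries, while Cox6a2 was at most 3.39 in Ado KO and at least 4.61 in control.

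The last question was whether the response to TNF itself differed between the genotypes. At 1 h limma called 0 genes for the interaction of genotype and TNF, 0 with guide populations as fixed terms, and 22 without Ado KO TNF 1 h 2-2. At an unadjusted p below 0.05, limma gave 1304 of 13272 genes at 1 h. At 6 h it called 46 genes, all with a lower response in Ado KO. Of these, 34 were small non-coding RNAs, 26 of them nucleolar, such as Snora30 (-1.55 ± 0.19, SE; adjusted p = 2.3e-05), Snora47 (-1.57 ± 0.24, SE; adjusted p = 6.2e-04) and Snord13 (-1.60). Snhg17 (-1.67), a host transcript of small nucleolar RNAs, and 5 models annotated as microRNA were called with them. Gm12238 and Gm22884 had identical values (-1.33 ± 0.25, SE), so the 46 genes are not all separate signals. The protein-coding genes called were Lars2 (-1.24) and the integrin gene Itga11 (-3.58 ± 0.80, SE, limma adjusted p = 0.0289). The Ado KO means of Itga11 were 0.26 at 6 h and 0.42 untreated, close to the bottom of the scale. Its call ended in 9 of 16 fits without a library. Lars2 was named after its value was seen. At 6 h Lars2 rose by 3.20 in control and 1.96 in Ado KO cells, where small non-coding RNAs had medians of 2.17 and 1.21.

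None of the 27 NF-kB feedback genes or 11 chemokines was called by limma for the 6 h interaction, also when adjusted over the list alone (0 in each; 3 higher feedback genes and 1 higher and 2 lower chemokines at an unadjusted p below 0.05), and 1 interferon-stimulated gene was higher when adjusted over the list alone. Camera called the mitochondrially encoded list as lower at 1 h (adjusted p = 1.2e-04) and 6 h (3.6e-05), with an adjusted p of 0.163 and 0.115 with an estimated correlation. With guide populations as fixed terms, which leaves the spread between guides out of the error, limma called 70 genes at 6 h, 2 higher and 68 lower. With 1 value per guide population it called 12, without control guide 1 it called 7 and without Ado guide 2 it called 1, against 64 without control guide 2 and 45 without Ado guide 1. Among 10746 protein-coding genes normalised again it called 0 (577 at an unadjusted p below 0.05), where 2 of the 46 were of that class before. Over all genes the count was 27 without control TNF 6 h 1-1 and 30 without Ado KO untreated 2-1.

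The populations of a genotype were also compared with each other, in the untreated state. Control guide 2 differed from control guide 1 in 119 genes, 60 higher and 59 lower, and Ado guide 2 from Ado guide 1 in 16, 13 higher and 3 lower, by limma with 2 libraries per population. Leaving out any of the 4 control libraries left 22 to 31 genes, namely 30 without 1-1, 29 without 1-2, 31 without 2-1 and 22 without 2-2. For the Ado guides the count was 10 without 1-1, 0 without 1-2 and 1 without 2-1.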

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

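Chosen after the results were seen were the tests of histone messages, of TNF itself, of protein-coding genes alone and of the NF-kB response as explanations.

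After 6 h of TNF, small non-coding RNAs rose in both genotypes, and the 8 libraries at 6 h had a share of them above that of every other library. Reads shared between copies of an RNA family are argued against, because 48 of these RNAs with no similar transcript of another gene had a median log2 fold change of 2.81 in control cells. That non-polyadenylated RNA of all kinds entered the 6 h libraries stays open: histone messages, which mostly lack a poly(A) tail, had a median of 1.61, above the highest of 10000 random lists of matched genes (0.0897). It leaves unexplained that 4 of 20 H2A and 0 of 5 H1 genes rose by limma (0 H1 genes at an unadjusted p below 0.05). An effect of TNF on these RNAs in the cells cannot be told apart from a difference in handling of the 6 h samples, since no untreated 6 h library was among those analysed.

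The rise of small RNAs at 6 h was smaller in Ado KO, where 34 of the 46 genes called for the interaction were small non-coding RNAs (of all genes, 12 were called with 1 value per guide population, 7 without control guide 1 and 1 without Ado guide 2), and nucleolar RNAs differed from control by a median of 0.46 in untreated cells (65 higher and 2 lower of 228 at an unadjusted p below 0.05) and -0.63 at 6 h. A weaker NF-kB response of Ado KO cells at 6 h stays open, as 2 populations per genotype are too few to decide: the mean response differed by 0.050 over both fixed lists, by 0.16 for the feedback list (Ado guides 1.04 and 1.06, control guides 0.84 and 0.95) and by -0.22 for the chemokine list (2.32 and 2.07 against 2.54 and 2.29, with 6 of 11 genes above 0). A lower share of the same RNAs in the Ado KO libraries at 6 h stays open too. Limma called 0 interaction genes among 10746 protein-coding genes normalised again (577 at an unadjusted p below 0.05). Only 2 of the 46 calls were of that class before, so the test had no way to come out otherwise. Whether that share arose in the cells or in library preparation was not tested. The share also differed between control guides, at 3.35 and 3.28% for guide 1 and 2.36 and 2.18% for guide 2.

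Genes that differed between Ado KO and control could reflect Ado or differences between guide populations unrelated to Ado. Grouping the populations another way, with a control and an Ado guide on each side, called at most 1 gene in untreated libraries and 0 at 1 h and 6 h by limma, against 33, 141 and 135 for genotype. Guides of the same genotype also differed in untreated libraries. Limma with guide populations as fixed terms called 119 genes between the control guides and 16 between the Ado guides. That fit called 132 for genotype, with 4 libraries on each side against 2 for a comparison of guides. The counts thus differ in power and do not compare the sizes of the differences. Neither control guide targets Ado, so the 119 genes between them did not come from an Ado guide. With 4 populations there are 3 groupings, so an effect of Ado and differences between guide populations cannot be told apart. The Ado level gives no check, as tags at the 3' end need not change with an edit.

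Other splits of the same libraries were counted for each comparison, 35 splits of 8 libraries or 100 for an interaction, the real one included. In every comparison named next 1 split, the real one, reached its count. For the TNF comparisons chance can be excluded over free splits of the libraries, which may be technical replicates. Within guide populations it is not excluded, since 17 other splits keep 2 libraries of each population on each side, with at most 1 (control 1 h), 1 (control 6 h), 3 (Ado KO 1 h) and 1 (Ado KO 6 h) genes, and with the real one they are too few for a share under 0.05. For genotype and the 6 h interaction this holds for splits of single libraries, but the libraries come in pairs from 4 populations with 3 groupings, too few for a share under 0.05, so chance between populations is not excluded. The real counts and the highest other were 52 and 29 (control 1 h), 2392 and 2 (control 6 h), 34 and 3 (Ado KO 1 h), 855 and 1 (Ado KO 6 h), 33 and 1 (genotype, untreated), 141 and 136 (genotype, 1 h), 135 and 1 (genotype, 6 h) and 46 and 36 (interaction, 6 h). For the interaction at 1 h limma called 0 genes (1304 of 13272 at an unadjusted p below 0.05), and the highest other split gave 14. Any split reaches a count of 0, so the 100 of 100 splits that did are no test. Chance is not excluded there. The control split that called 29 genes parted guide 1 from guide 2, and with guide populations as fixed terms the control 1 h comparison called 216. For genotype at 1 h the splits with 136, 135 and 67 genes each put Ado KO TNF 1 h 2-2 with control libraries, which points to a structure of the samples, and the count was 445 without that library, 3 with only the groups compared in the fit and 6 with 1 value per guide population. Cox6a2 was 2.79 in that library, within the range of the Ado KO libraries.

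Of 66 combinations of a group of 4 libraries and a measure, which share the same 24 libraries and are not independent, 5 had a library far from the others, where chance gives about 1 in 20. The mitochondrial share was 3.58% in control TNF 1 h 1-2 against 2.55 to 2.66% in the other libraries of its group, 2.4% in Ado KO untreated 1-1 against 2.05 to 2.1%, and 2.48% in Ado KO TNF 1 h 2-2 against 1.84 to 1.91%. Ado was 5.00 in Ado KO TNF 6 h 2-1 against 5.37 to 5.43, and Nfkbia was 7.63 in Ado KO untreated 1-1 against 7.46 to 7.47.

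The response to 6 h of TNF differed between genotypes by the interaction test for Itga11 (-3.58), Snord92 (-2.84), Snora62 (-2.02), Snora3 (-1.81), Snora68 (-1.77), Snhg17 (-1.67), Snord13 (-1.60), Snora47 (-1.57), Snora30 (-1.55) and Snora20 (-1.53), each lower in Ado KO on the log2 scale. With each of 16 libraries left out in turn, the calls of Snord92 ended in 10 of the fits, Itga11, which lies near the bottom of the scale, in 9, Snora62 in 5, Snora68 in 2 and the others in 0.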

How the results depend on the processing

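Chosen after the results were seen were the settings with protein-coding genes alone and with the guide population as an additive term.

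Under the other settings no named gene reversed its direction: 3729 results of named genes kept direction and side of the threshold and 595 fell short of it, and with 1 library left out these were 2063 and 465. Only genes called in the main fit were counted. The largest rises and falls among them also had to share a sign in every guide population. A reversal was therefore unlikely from the start, and its absence is no test of the results. Median centring, another quantile normalisation, no filter, a stricter filter, no guide block, robust variances and the replicate block moved no count of called genes by over 1.5 times. The cause was not tested for the changes below unless the setting itself states it, such as fewer libraries. A pseudocount and tests on counts did not apply to log2 values. The estimated depth limits genes near the lowest value, and in simulated data 14.9% of genes with a 1.5-fold interaction at 6 h were recovered.

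Counts of called genes in the order control 1 h, control 6 h, Ado KO 1 h, Ado KO 6 h, genotype untreated, genotype 1 h, genotype 6 h, interaction 1 h and interaction 6 h were 52, 2392, 34, 855, 33, 141, 135, 0 and 46. Comparisons absent from a sentence stayed within 1.5 times. With variances without a trend, genotype called 6 (untreated), 43 (1 h) and 58 (6 h), the 6 h interaction 30, control guides 20 and Ado guides 0 (1231 at an unadjusted p below 0.05 with the trend, by limma). With guide populations as fixed terms, 12 means, the counts were 216 (control 1 h), 57 (Ado KO 1 h), 132, 609 and 324 (genotype) and 70 (6 h interaction), and no other call count moved by over 1.5 times. This fit leaves the spread between guides out of the error. With 1 value per guide population genotype called 2, 6 and 28 and the 6 h interaction 12. With the guide population as an additive term control 1 h called 83. With only the groups compared in the fit the counts were 28 (control 1 h), 20 (Ado KO 1 h), 13, 3 and 295 (genotype) and 73 (6 h interaction). Over 2-fold they were 20 (control 1 h), 667 (control 6 h), 21 (Ado KO 1 h), 370 (Ado KO 6 h), 4, 25 and 36 (genotype), 41 (control guides) and 4 (Ado guides).

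Leaving out control guide 1 gave 22 (control 1 h), 684 (control 6 h) and 7 (6 h interaction). Leaving out control guide 2 gave 260 (control 1 h), 1575 (control 6 h), 139, 956 and 322 (genotype) and 7 (1 h interaction). Leaving out Ado guide 1 gave 369 (Ado KO 6 h), 23 (genotype 1 h) and 37 (genotype 6 h). Leaving out Ado guide 2 gave 15 (Ado KO 1 h), 417 (Ado KO 6 h), 3, 71 and 31 (genotype) and 1 (6 h interaction). Among protein-coding genes alone the counts were 1414 (control 6 h), 90 (genotype 1 h), 38 (genotype 6 h) and 0 (6 h interaction, 577 at an unadjusted p below 0.05 by limma), where the same genes gave 617 higher and 1190 lower, 37 and 60, 48 and 18, and 0 and 2 before.

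With 1 library left out the ranges were 31 to 84 (control 1 h; 31 without control untreated 1-1, 34 without 1-2 and 84 without control TNF 1 h 2-1), 1583 to 2151 (control 6 h; 1583 without control untreated 1-1), 26 to 44 (Ado KO 1 h) and 693 to 728 (Ado KO 6 h). For genotype they were 11 to 35 untreated (11 and 12 without control 1-1 and 1-2, 13 without Ado KO 2-2), 30 to 445 at 1 h (78 without control 1-1, and 65, 60, 30 and 445 without Ado KO 1-1, 1-2, 2-1 and 2-2) and 57 to 139 at 6 h (57 and 68 without control 1-1 and 1-2, and 75, 58 and 66 without Ado KO 1-2, 2-1 and 2-2). The interactions gave 0 to 22 at 1 h (22 without Ado KO TNF 1 h 2-2) and 27 to 54 at 6 h (27 without control TNF 6 h 1-1 and 30 without Ado KO untreated 2-1). Control guides gave 22 to 31, from 119, for each of the 4 libraries, and Ado guides 0 to 17, from 16 (10, 0 and 1 without 1-1, 1-2 and 2-1). The Ado difference in untreated cells was 0.07 to 0.12. Where a guide population was left with 1 library, that library was assumed to vary like the others.

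Camera with an estimated correlation called 0 lists for genotype untreated in place of 6, 2 at 1 h in place of 4, 2 at 6 h in place of 4, and 0 for each interaction in place of 1. The difference in mean NF-kB response was -0.041 for the feedback list and -0.59 for the chemokine list at 1 h, in place of -0.20, and 0.16 and -0.22 at 6 h, in place of 0.05.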

Other observations

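The comparisons of 6 h with 1 h of TNF were chosen after the data were seen. In control cells Cxcl1 (log2 fold change -1.44, limma adjusted p = 0.0135), Zfp36 (-1.05, adjusted p = 6.4e-04), Dusp8 (-1.01, adjusted p = 0.0156) and Irf1 (-0.58, adjusted p = 1.3e-04) fell between 1 h and 6 h, while Nfkbia (-0.11, adjusted p = 0.457) and Tnfaip3 (-0.94, adjusted p = 0.155) did not pass the test. Vcam1 (1.62, adjusted p = 9.2e-15), Ccl2 (1.75, adjusted p = 1.8e-04), Relb (1.39, adjusted p = 4.5e-13) and Lif (2.94, adjusted p = 0.00132) rose over the same time. Etv1, a transcription factor gene, fell by 2.23 (adjusted p = 5.4e-08).

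In Ado KO cells Zfp36 (-0.97, adjusted p = 0.00223) and Jun (-0.22, adjusted p = 0.0406) fell between 1 h and 6 h, and Cxcl1 (-1.01, adjusted p = 0.109), Dusp8 (-0.77, adjusted p = 0.0792) and Irf1 (-0.16, adjusted p = 0.39) did not pass. Vcam1 (1.60, adjusted p = 1.6e-14), Relb (1.45, adjusted p = 3.6e-13) and Lif (3.33, adjusted p = 4.0e-04) rose, and Chst1 fell by 1.97 (adjusted p = 1.8e-15). Limma called 1019 genes in control cells, 640 higher and 379 lower, and 1031 in Ado KO cells, 537 higher and 494 lower. Small non-coding RNAs were 245 higher and 1 lower in control cells, and 118 higher and 5 lower in Ado KO cells. Among protein-coding genes without histone genes the falls outnumbered the rises. There 305 were higher and 349 lower in control cells, and 354 higher and 436 lower in Ado KO cells. Whether these changes differed between the genotypes was not tested.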
